A study of Homo sapiens with 103 samples.

How the data were processed

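RNA-seq was measured in T47D, a luminal breast cancer cell line that expresses estrogen receptor. Per the labels' protocols, cells were grown without hormones for 3 days and then received 10 nM estradiol (E2, the main estrogen), and total RNA was sequenced with a stranded protocol that removes ribosomal RNA. The 36 libraries analysed here form 18 groups of 2 in 6 lines. The lines shCtrl (a control short hairpin RNA) and shRING1B (a hairpin against RNF2, the gene of RING1B) were sampled at 0, 4, 8, 12 and 24 h of E2 from 500 ng of RNA. The parental line and the lines R98A, I53A and rescue were sampled at 0 and 24 h from 250 ng of RNA. R98A and I53A carry the RNF2 hairpin and a tagged mutant RING1B, and rescue carries the hairpin and wild-type RING1B. Per the labels' protocols, these 3 lines were sorted for a fluorescent marker. The protocol text of the I53A line at 24 h names an I98A plasmid, and these libraries were analysed as I53A by their titles. The protocol text of the rescue line at 24 h names no E2, which the description of the series design does give. The other 67 of the 103 samples in the labels, from assays of chromatin, were not analysed here.

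The submitters' processing notes name the genome build hg19 and, among other tools, cutadapt 1.9.1 and 2.3, STAR 2.7.1a and RSEM 1.3.0, without a role for each. Per the file headers, the values are the gene-level output of RSEM. The authors deposited expected counts, which are estimates of the number of fragments per gene, together with other columns that were not used. The annotation release and the strand setting of the counting are not given in the sources used here. Each file held 57820 genes under Ensembl identifiers, 51996 of which were paired with a symbol by identifier in the table of gene names. The other genes kept the symbol given in the files. A total of 289 symbols were shared by 2344 genes. No spike-in was among the identifiers.

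The total expected count per library was 19504316 to 25279224 in shCtrl and shRING1B, 13888897 to 25780445 in parental, R98A and I53A, and 27624881 to 31579212 in rescue. Levels are given in CPM, the count scaled to a common effective library size by edgeR, as the mean with the standard deviation (SD) of the 2 libraries of a group. A fold change is given on the log2 scale with its standard error (SE), taken from the fold change and the F statistic. The p-values measure the spread between these samples, since the labels do not state whether the 2 libraries of a group came from separate cultures.

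Rounded expected counts were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with robust estimation, trimmed-mean scaling and 1 coefficient per group. The filter of edgeR kept genes by a minimum count of 10 and a minimum total of 15. One fit held the 20 shCtrl and shRING1B libraries, another the 12 parental, R98A and I53A libraries, and a further fit the 12 shCtrl, shRING1B and rescue libraries at 0 and 24 h. For the closing section, 1 more fit held the 16 parental, R98A, I53A and rescue libraries, and another the 12 libraries of all lines at 0 h. Genes were called at an adjusted p under 0.05. The 37 comparisons were the E2 response of each line at each time against its own 0 h, pairs of lines at the same time, the average of shRING1B against shCtrl over the 5 times, and differences between E2 responses. The groups, comparisons, gene lists and the rule for named genes were chosen before the data were examined.

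The strength of the E2 response was compared between lines with limma's fry test, which asks whether a set of genes moves on balance 1 way. Each set was chosen in the other experiment, from parental for shCtrl, shRING1B and rescue, and from shCtrl for parental, R98A and I53A, so that no library served both to choose and to test. Adjustment was over the 18 tests. The overlap of the genes called in R98A and in I53A against parental was compared with the number that independent calls would share and with 5 draws of simulated counts, since both comparisons use the same controls.

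A total of 22 gene lists were tested in every comparison with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a comparison. The lists were estrogen-induced genes; estrogen-repressed genes; G1/S and DNA replication genes; G2/M and mitosis genes; replication-dependent histone genes; ribosome biogenesis and MYC target genes; PRC1 subunit genes; PRC2 subunit genes and developmental Polycomb target genes. They also held estrogen receptor cofactor and luminal transcription factor genes, luminal epithelial markers, basal epithelial markers, mesenchymal and fibroblast markers, leukocyte markers, interferon response genes, NF-kB and inflammatory genes, immediate early genes, p53 target and apoptosis genes, cholesterol and lipid synthesis genes, unfolded protein response and ATF4 target genes, hypoxia and glycolysis genes, and mitochondrially encoded genes. They came from textbook knowledge, not from these libraries, and some genes are in more than 1 list.

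Named genes were the 8 with the largest rise and the 8 with the largest fall among called genes with an average log2 CPM of at least 2 and no overlap between the libraries of the compared groups. For a difference of E2 responses, the 4 differences between libraries of 1 line did not overlap those of the other. Symbols of clones, antisense or small RNAs, pseudogenes and open reading frames were left aside. To these were added the up to 4 members of each described list with the smallest p, and RNF2, RING1, ESR1, PGR, GREB1 and TFF1 in every comparison.

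The alternatives tried were the size factors of DESeq2, the Wald test of DESeq2 1.42.0, no filter, the replicate number as a block, only the compared groups in the fit, leaving out each library in turn, the 100 genes of largest change per set, fry in place of camera, an estimated correlation, and a change of at least 1.5-fold for the overlap. The main axis of the differences between replicates as a covariate, and the E2 strength without shCtrl 8 h replicate 1 and shCtrl 24 h replicate 1, were added after seeing the data. In simulated data with 200 changed genes, true 2-fold changes were recovered in 40.3% of cases for the E2 response of shRING1B at 24 h and 64.2% for that of R98A, but in 14.9% for a difference of E2 responses between shRING1B and shCtrl. A check of 60 unchanged simulated sets with camera gave 2 with p under 0.05. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.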

Results

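RNA was sequenced from T47D cells that were deprived of hormone for 3 days and then given E2, to ask what RING1B contributes to the estrogen response. RING1B is the catalytic subunit of Polycomb repressive complex 1 (PRC1), which places ubiquitin on histone H2A. Per the labels, 2 libraries were made for each of 18 groups: shCtrl and shRING1B at 0, 4, 8, 12 and 24 h, and parental, R98A, I53A and rescue at 0 and 24 h. R98A is a change in RING1B known to disrupt its binding to nucleosomes, and I53A is known to disrupt its interaction with the ubiquitin-conjugating enzyme. Adjusted p-values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. Libraries held 13888897 to 31579212 expected counts, and the mitochondrially encoded share ranged from 1.524% to 9.778%.

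RNF2, the RING1B gene (ENSG00000121481.6), was measured first in every line, since each comparison rests on its level. It stood at 21.11 ± 0.78 CPM in shCtrl (SD, n = 2) and 6.035 ± 0.192 CPM in shRING1B at 0 h. Averaged over the 5 times it was lower in shRING1B by a log2 fold change of -1.89 ± 0.10 (SE; adjusted p = 3.5e-11). Parental cells held 26.53 ± 3.65 CPM at 0 h, R98A 137.0 ± 16.5, I53A 482.5 ± 99.3 and rescue 282.3 ± 33.3 (SD, n = 2 each). RNF2 was thus above parental in R98A (2.37 ± 0.19, adjusted p = 3.1e-06) and in I53A (4.18 ± 0.20, adjusted p = 1.2e-07), and above shCtrl in rescue (3.71 ± 0.16, adjusted p = 7.8e-08). RING1, the paralog that can take the place of RING1B in PRC1, was higher in shRING1B on average over the 5 times (0.38 ± 0.07, adjusted p = 2e-04), but missed the threshold at 4 and 12 h (0.17 and 0.05, adjusted p = 0.48 and 0.86). The counts do not tell hairpin-resistant RNF2 from the endogenous transcript.

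**Figure D1:**
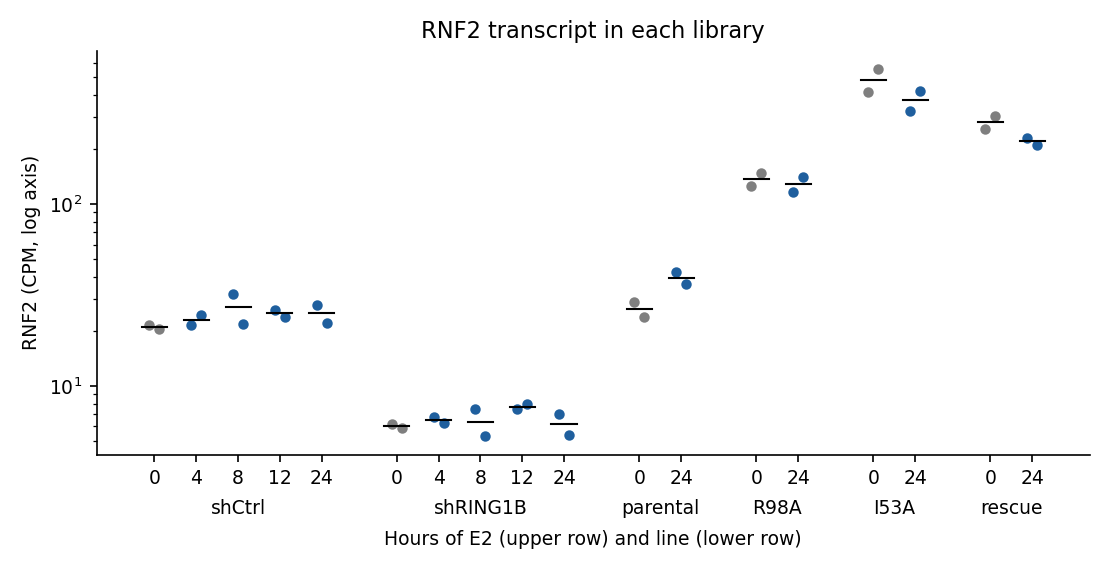
RNF2 in CPM on a log axis in each of the 36 libraries (points), with group means (lines), for the 6 lines by hours of E2. The shRING1B libraries lie below all others, with a mean of 6.035 at 0 h, and the R98A, I53A and rescue libraries lie above parental, with means of 137.0, 482.5 and 282.3 at 0 h.

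The shCtrl cells showed which genes changed after E2 with RING1B present. Every E2 response in this text compares a later time with E2 against 0 h without it. No line had libraries without E2 at a later time. The effect of the hormone was therefore not separated from that of further time in culture and handling. CXCL12, a chemokine gene, went from 7.666 ± 0.218 CPM at 0 h to 119.8 ± 4.91 at 24 h (SD, n = 2), a log2 fold change of 3.97 ± 0.20 (adjusted p = 8.3e-09). OLFM1, which encodes a secreted glycoprotein, rose by 3.14 ± 0.20 (adjusted p = 5.5e-08), and ADRA2A, an adrenergic receptor gene, rose by 2.80 ± 0.26 (adjusted p = 2.9e-06). The classical targets followed, and PGR, the progesterone receptor gene, rose by 1.24 ± 0.13 (adjusted p = 1.1e-05). GREB1, an estrogen receptor coactivator gene, rose by 2.01 ± 0.21 (adjusted p = 1.4e-05) and TFF1, a secreted trefoil peptide gene, by 1.67 ± 0.34 (adjusted p = 0.0033). IL1R1, the interleukin-1 receptor, fell to a log2 fold change of -1.85 ± 0.17 (adjusted p = 3.7e-06). ABCA1, a cholesterol exporter, fell to -1.82 ± 0.21 (adjusted p = 2.5e-05) and FBXO32, a ubiquitin ligase gene of atrophy, to -1.77 ± 0.16 (adjusted p = 2.4e-06). Other large rises were in KCNK5, SLC47A1 and NPY1R (2.86 to 2.96), and other large falls in CDH10, FGF12 and TM4SF18 (-1.82 to -1.73). ESR1, the estrogen receptor gene itself, was at -0.13 ± 0.15 (adjusted p = 0.69). The TFF1 call was lost without 0 h replicate 1 (1.59, adjusted p = 0.053). AREG (5.78 ± 1.35, adjusted p = 0.02), a growth factor gene with a near-identical copy, was lost without any 1 of the 4 libraries, with adjusted p of 0.061 to 0.17. HIST1H4K, a histone gene (2.96 ± 0.62, adjusted p = 0.0097), was lost without 0 h replicate 1 (adjusted p = 0.061), 0 h replicate 2 (0.13) or 24 h replicate 2 (0.089).

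Called genes were counted at each time in shCtrl. At 4 h, 102 genes were called, 70 higher and 32 lower. Among them were CXCL12 (3.45 ± 0.20, adjusted p = 6.2e-08), STC2, a stanniocalcin gene (1.53 ± 0.15, adjusted p = 4.4e-05), and NRIP1, a receptor corepressor gene (0.62 ± 0.11, adjusted p = 0.014). At 8 h 258 genes were called (183 higher), at 12 h 615 (325 higher) and at 24 h 2068 (1322 higher, 746 lower). With only the compared groups in the fit the counts were 301, 36, 4017 and 1312 at the 4 times. Counts depended on single libraries: at 4 h they were 42, 40, 57 and 43 without 0 h replicate 1, 0 h replicate 2, 4 h replicate 1 or 4 h replicate 2. At 8 h they were 93 and 88 without 0 h replicate 1 or 2. At 12 h they were 141, 118, 251 and 113 without 0 h replicate 1, 0 h replicate 2, 12 h replicate 1 or 12 h replicate 2. At 24 h they were 1030, 875 and 1247 without 0 h replicate 1, 0 h replicate 2 or 24 h replicate 2. The 4 h call of NRIP1 was lost without any 1 of the 4 libraries, with adjusted p of 0.1 to 0.22.

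**Figure D2:**
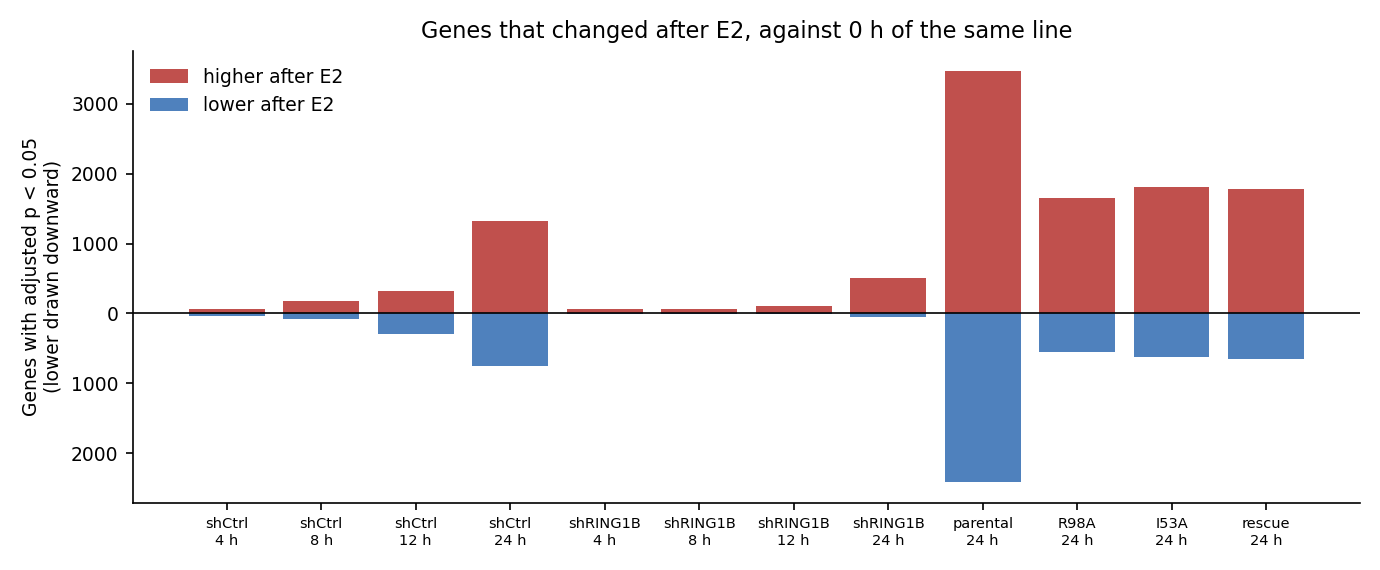
Number of genes called after E2 against 0 h in each line (bars up, higher; bars drawn downward, lower; adjusted p under 0.05), for 12 comparisons. At 24 h the bars reach 1322 higher and 746 lower genes in shCtrl, and 510 and 56 in shRING1B. Bars from separate fits differ in precision and are not directly comparable.

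Cell-division genes rose together in shCtrl at 24 h. All 30 G2/M and mitosis genes rose (30 adjusted over the list alone; median 1.78, adjusted p = 0.037 with an estimated correlation), with KIF11, a mitotic motor, at 1.84 ± 0.16 (adjusted p = 2.3e-06). Of 30 G1/S and DNA replication genes, 29 rose (30 adjusted over the list alone; median 1.55, adjusted p = 0.031 with an estimated correlation). TYMS, which makes thymidylate, was at 1.93 ± 0.21 (adjusted p = 1.4e-05) and the helicase subunit MCM4 at 1.28 ± 0.13 (adjusted p = 7.9e-06). Of 35 estrogen-induced genes, 28 rose and 0 fell by edgeR (31 and 0 adjusted over the list alone; adjusted p = 0.0015 with an estimated correlation), with PDZK1, a scaffold protein gene, at 2.64 ± 0.14. Of 17 estrogen-repressed genes, 8 fell (9 adjusted over the list alone; adjusted p = 0.012 with an estimated correlation), among them BCAS1 at -1.57 ± 0.19 and the receptor tyrosine kinase gene ERBB2 at -0.97 ± 0.18 (adjusted p = 0.0022). Replication-dependent histone genes rose in 13 of 18 (16 adjusted over the list alone; camera adjusted p = 3.7e-15, but adjusted p = 0.084 with an estimated correlation). Ribosome biogenesis and MYC target genes rose in 8 of 30 (11 adjusted over the list alone; adjusted p = 0.037 with an estimated correlation), with NOP56, a snoRNP core gene, at 0.75 ± 0.13 (adjusted p = 0.0013).

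Polycomb genes moved in part after E2 in shCtrl. Of 13 PRC2 subunit genes, 6 rose (7 adjusted over the list alone, with 1 lower; adjusted p = 0.032 with an estimated correlation), led by EZH2, the H3K27 methyltransferase, at 1.48 ± 0.17 (adjusted p = 2.5e-05). Of 27 PRC1 subunit genes, 5 rose (5 adjusted over the list alone; camera adjusted p = 0.057). BMI1 was at 1.00 ± 0.22 (adjusted p = 0.0076), a call lost without 0 h replicate 2 (adjusted p = 0.12) or 24 h replicate 1 (0.08). Developmental Polycomb target genes rose in 3 of 33 and fell in 1 (4 and 1 adjusted over the list alone; camera adjusted p = 0.016, but adjusted p = 0.21 with an estimated correlation). WT1 was at 1.93 ± 0.32 (adjusted p = 0.00063).

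The shRING1B line differed from shCtrl in many genes at every time. A single hairpin line stood against a single control line, so the hairpin was not separated from other differences between them. PEG10, an imprinted gene derived from a retrotransposon, stood at 82.2 CPM in shCtrl and 2354 ± 159 in shRING1B at 0 h (SD, n = 2). Over the 5 times it was higher by 4.50 ± 0.06 (SE; adjusted p = 4.1e-18). BCHE, the butyrylcholinesterase gene, was higher by 5.16 ± 0.10 (adjusted p = 3.1e-16), SLITRK6, a neuronal membrane protein gene, by 5.40 ± 0.14 (adjusted p = 5.9e-14) and the potassium channel gene KCNJ3 by 5.82 ± 0.23 (adjusted p = 1.6e-12). Lower in shRING1B were S100A8, a calcium-binding alarmin gene, at -7.01 ± 0.22 (adjusted p = 1.7e-13), and BCL2, the survival factor gene and an estrogen target, at -5.33 ± 0.20 (adjusted p = 4.1e-12). So was SERPINA6, which encodes corticosteroid-binding globulin, at -4.21 ± 0.14 (adjusted p = 8.9e-12). PPP1R3C, LMO3, PCDH18 and LRRC31 were also higher (3.76 to 4.63), and S100A14, MAOB, PSG9, IVL and ABCA4 lower (-5.39 to -4.30). At 0 h, shRING1B was also set against parental cells, which came from another experiment and RNA input. S100A14, MAOB and PCDH18 missed the threshold there (0.71, 1.7 and 0.15, adjusted p = 0.15, 0.23 and 0.75). The other genes named so far in this paragraph passed in the same direction as against shCtrl. By the rule for named genes, the libraries of shRING1B and shCtrl did not overlap within any of the 5 times for the genes named here. In all, 9557 of 22118 tested genes were called, 4746 higher and 4811 lower, of which 1038 and 1549 differed at least 2-fold. At single times 2855 (0 h), 4181 (4 h), 3305 (8 h), 3931 (12 h) and 3625 (24 h) genes were called. With only the compared groups in the fit 4448, 548, 6941 and 1955 were called at 0, 8, 12 and 24 h. At 0 h they were 1330, 1771, 1664 and 1830 without shCtrl replicate 1, shCtrl replicate 2, shRING1B replicate 1 or shRING1B replicate 2, and in the same order 2217, 2238, 2003 and 2372 at 12 h. At 4 h they were 2620, 2492 and 2089 without shCtrl replicate 1, shCtrl replicate 2 or shRING1B replicate 1, and at 8 h 2038 without shRING1B replicate 2. At 24 h they were 2108, 1822 and 2106 without shCtrl replicate 1, shRING1B replicate 1 or shRING1B replicate 2. The count averaged over times was at least 8916 without any 1 library.

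Many estrogen receptor targets were lower in shRING1B on average over the 5 times. ESR1 was lower by -0.62 ± 0.07 over the 5 times (adjusted p = 5.9e-07), GREB1 by -0.88 ± 0.09 (adjusted p = 6.6e-07), PGR by -0.37 (adjusted p = 4.7e-05) and TFF1 by -2.37 ± 0.16 (adjusted p = 2.2e-09). At single times PGR missed the threshold at 0, 12 and 24 h (adjusted p = 0.052, 0.34 and 0.25), as did ESR1 at 24 h (adjusted p = 0.055). Among 35 estrogen-induced genes 29 were lower and 2 higher (29 and 2 adjusted over the list alone; camera adjusted p = 4.4e-14, but adjusted p = 0.07 with an estimated correlation). PDZK1 was at -3.31 ± 0.07 (adjusted p = 5.2e-16), STC2 at -2.86 ± 0.07 (adjusted p = 4.8e-15) and CCND1, the cyclin D1 gene, at -2.15 ± 0.07 (adjusted p = 6.6e-14). The 3457 genes that parental cells induced with E2 had a median of -0.05 at 0 h (quartiles -0.33 and 0.19). Estrogen-repressed genes went both ways, 5 higher and 8 lower (5 and 8 adjusted over the list alone; camera adjusted p = 0.23). Of G1/S and DNA replication genes 23 of 30 were lower and 1 higher (23 and 1 adjusted over the list alone; camera adjusted p = 1.2e-05, but adjusted p = 0.41 with an estimated correlation), with CDC6 at -1.21 ± 0.12. Of G2/M and mitosis genes 19 were lower (20 adjusted over the list alone; camera adjusted p = 1.8e-05, but adjusted p = 0.5 with an estimated correlation), with HMMR at -1.09 ± 0.10.

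PRC1 subunit genes went both ways with the knockdown, 11 higher and 7 lower (11 and 7 adjusted over the list alone; camera adjusted p = 0.48). CBX6 was higher by 2.11 ± 0.09 (adjusted p = 1.8e-11) and RYBP by 0.62 ± 0.08 (adjusted p = 9.6e-06), while AUTS2 was lower by -1.07 ± 0.08 (adjusted p = 1.1e-08). PRC2 subunit genes split into 3 higher and 5 lower (4 and 5 adjusted over the list alone; camera adjusted p = 0.67), with SUZ12 at -0.62 ± 0.08 (adjusted p = 3.1e-06). Of 33 developmental Polycomb target genes, 17 were lower and 3 higher (17 and 3 adjusted over the list alone; camera adjusted p = 0.00083, but adjusted p = 0.25 with an estimated correlation). The pluripotency factor gene SOX2 was higher by 4.10 ± 0.33 (adjusted p = 3.4e-08), while the kidney transcription factor gene WT1 was at -2.42 ± 0.16 (adjusted p = 8.4e-10) and HOXB3 at -0.80 ± 0.08 (adjusted p = 1.2e-07). No list of the 22 held its call with an estimated correlation in this comparison, while 17 passed fry, which asks only whether a list moves on balance 1 way.

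Estrogen targets still rose after E2 when RING1B was depleted. At 24 h CXCL12 rose by 4.13 ± 0.21 in shRING1B (adjusted p = 6.1e-09), OLFM1 by 3.38 ± 0.20 (adjusted p = 5.5e-08) and PGR by 1.41 (adjusted p = 1.1e-05). GREB1 rose by 1.96 ± 0.21 (adjusted p = 8.9e-05) and TFF1 by 3.35 ± 0.41 (adjusted p = 0.00022). MYC, the growth-promoting transcription factor gene, rose by 2.98 ± 0.29 (adjusted p = 2.5e-05). Both TFF1 and MYC started lower in shRING1B than in shCtrl, at 0.58 against 5.52 CPM and 2.72 against 16.4 CPM at 0 h. At 24 h they stood at 5.93 against 17.6 CPM and 21.5 against 34.6 CPM. Estrogen-induced genes rose in 20 of 35 (26 adjusted over the list alone, with 1 lower; adjusted p = 0.0024 with an estimated correlation). Estrogen-repressed genes fell in 3 of 17 (6 adjusted over the list alone; adjusted p = 0.018 with an estimated correlation). G1/S and DNA replication genes rose in 28 of 30 (30 adjusted over the list alone; adjusted p = 0.014 with an estimated correlation). Ribosome biogenesis and MYC target genes rose in 7 (20 adjusted over the list alone; adjusted p = 0.0034 with an estimated correlation). G2/M and mitosis genes rose in 12 (27 adjusted over the list alone; camera adjusted p = 2.8e-25, but adjusted p = 0.1 with an estimated correlation), with a median of 0.98. The number of calls depended on the setting. DESeq2's Wald test, no filter and the axis of replicate differences each gave more at every time, as listed in the section on processing. As reported, calls numbered 66 at 4 h, 64 at 8 h, 119 at 12 h and 566 at 24 h (510 higher, 56 lower). Without 1 library they were 28 and 26 at 4 h (0 h replicate 1, 4 h replicate 1), 29, 39 and 36 at 8 h (0 h replicate 1, 0 h replicate 2, 8 h replicate 2). They were 49, 68 and 52 at 12 h (0 h replicate 1, 12 h replicate 1, 12 h replicate 2), and 325, 150 and 117 at 24 h (0 h replicate 1, 0 h replicate 2, 24 h replicate 2).

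The test of the difference between the E2 responses of shRING1B and shCtrl called a number of genes that depended on the setting: 1 at 4 h, 2 at 8 h, 3 at 12 h and 3 at 24 h. THBS1, the thrombospondin gene, stood at 193.9 ± 24.1 CPM in shCtrl and 675.4 ± 106 in shRING1B at 0 h (SD, n = 2). At 24 h the levels were 1036 ± 112 and 1131 ± 39.6 CPM, a difference of responses of -1.67 ± 0.23 (SE; adjusted p = 0.012). PPM1K, a mitochondrial phosphatase gene, rose more in shRING1B (difference 1.26 ± 0.18, adjusted p = 0.02), from 37.17 ± 4.05 to 129.6 CPM against 43.9 ± 1.53 to 63.99 ± 10.3 in shCtrl. RBBP8, a DNA end resection gene chosen after its values were seen, differed by -1.62 ± 0.21 (adjusted p = 0.011). TFF1 had a difference of 1.67 ± 0.53 that missed the threshold (adjusted p = 0.65), as did PGR (0.16 ± 0.18) and GREB1 (-0.05 ± 0.28), both at adjusted p = 1. No member of a list was called, and G2/M and mitosis genes had a median difference of -0.83 (camera adjusted p = 8.6e-29, but adjusted p = 0.21 with an estimated correlation). DESeq2's Wald test called 9, 14, 25 and 56 genes at the 4 times. With no filter edgeR called 231, 107, 270 and 158, with only the compared groups 411 at 12 h, and with the axis of replicate differences, a setting added after seeing the data, 61 at 24 h. Without 1 library the count of 3 at 24 h was 0 (shCtrl 0 h replicate 2 or shRING1B 24 h replicate 1), 1 (shCtrl 0 h replicate 1, shCtrl 24 h replicate 2 or shRING1B 24 h replicate 2) or 5 (shCtrl 24 h replicate 1). The THBS1 call was lost without shCtrl 0 h replicate 1 (-1.55, adjusted p = 0.19), shCtrl 0 h replicate 2 (0.068), shCtrl 24 h replicate 2 (0.061), shRING1B 0 h replicate 2 (0.073), shRING1B 24 h replicate 1 (0.12) or shRING1B 24 h replicate 2 (0.075). The PPM1K call was lost without any 1 of the same 6 libraries (adjusted p of 0.075 to 0.2).

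As sets, the genes that parental cells induced with E2 showed no difference between shRING1B and shCtrl that passed fry. Median differences for the 3457 induced genes were -0.08, -0.02, -0.18 and -0.09 at 4, 8, 12 and 24 h (fry adjusted p = 0.58, 0.84, 0.14 and 0.24). The 2388 genes repressed in parental fell less in shRING1B at 12 h, with a median difference of 0.29 and 81.7% of them above 0 (fry adjusted p = 0.026). At 4, 8 and 24 h their medians were 0.20, 0.11 and 0.16 (fry adjusted p = 0.14, 0.24 and 0.14). The 12 h call was lost without shCtrl 0 h replicate 1 (0.064), shCtrl 0 h replicate 2 (0.086), shCtrl 12 h replicate 2 (0.093), shRING1B 0 h replicate 1 (0.082) or shRING1B 12 h replicate 1 (0.077), each an adjusted p.

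Parental cells gave the largest number of E2 calls, but numbers from separate fits cannot be set against each other directly. The median SE of the 24 h response was 0.206 in parental, 0.308 in shCtrl and 0.252 in rescue. Experiment and RNA input differ as well between parental and shCtrl. CXCL12 rose by 6.56 ± 0.21 (adjusted p = 5.8e-10), from 2.262 ± 0.0122 to 213.8 ± 7.87 CPM (SD, n = 2). OLFM1 rose by 4.84 ± 0.15 (adjusted p = 8.6e-11), SERPINA6 by 3.90 ± 0.18 (adjusted p = 2.5e-08) and MYB, a proliferation-linked transcription factor gene, by 3.18 ± 0.18 (adjusted p = 2e-08). PGR rose by 1.85 ± 0.14 (adjusted p = 2.2e-07), GREB1 by 2.21 ± 0.17 (adjusted p = 2.9e-06) and ESR1 by 0.55 ± 0.11 (adjusted p = 0.0019). SEMA6D, an axon guidance gene, fell to -2.82 ± 0.28 (adjusted p = 3.1e-06), and FBXO32 to -2.29 ± 0.16 (adjusted p = 4.7e-07), as did NDRG1, PCDH7, IL1R1 and STON1 (-2.56 to -2.17). Estrogen-induced genes rose in 31 of 34 and fell in 1 (32 and 1 adjusted over the list alone; adjusted p = 0.005 with an estimated correlation). Estrogen-repressed genes fell in 12 of 18 and rose in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.016 with an estimated correlation). All 30 G1/S and DNA replication genes rose (30 adjusted over the list alone; adjusted p = 0.052 with an estimated correlation). So did 30 G2/M and mitosis genes (30 adjusted over the list alone; adjusted p = 0.22 with an estimated correlation). Of 18 histone genes, 17 rose (17 adjusted over the list alone; adjusted p = 0.22 with an estimated correlation), as did 27 ribosome biogenesis genes (29 adjusted over the list alone; adjusted p = 0.052 with an estimated correlation). In all 5883 genes were called, 3466 higher and 2417 lower. TFF1 (4.16 ± 1.18, adjusted p = 0.036) was lost without any 1 of the 4 libraries, with adjusted p of 0.064 to 0.18. The fall of KCNJ3 (-2.53 ± 0.62, adjusted p = 0.013) was lost without 0 h replicate 1 (-1.75, adjusted p = 0.073) or 24 h replicate 1 (-2.04, adjusted p = 0.13). Mitochondrially encoded counts were 1.5% of the total in 24 h replicate 1 and 7.6% in replicate 2.

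**Figure D3:**
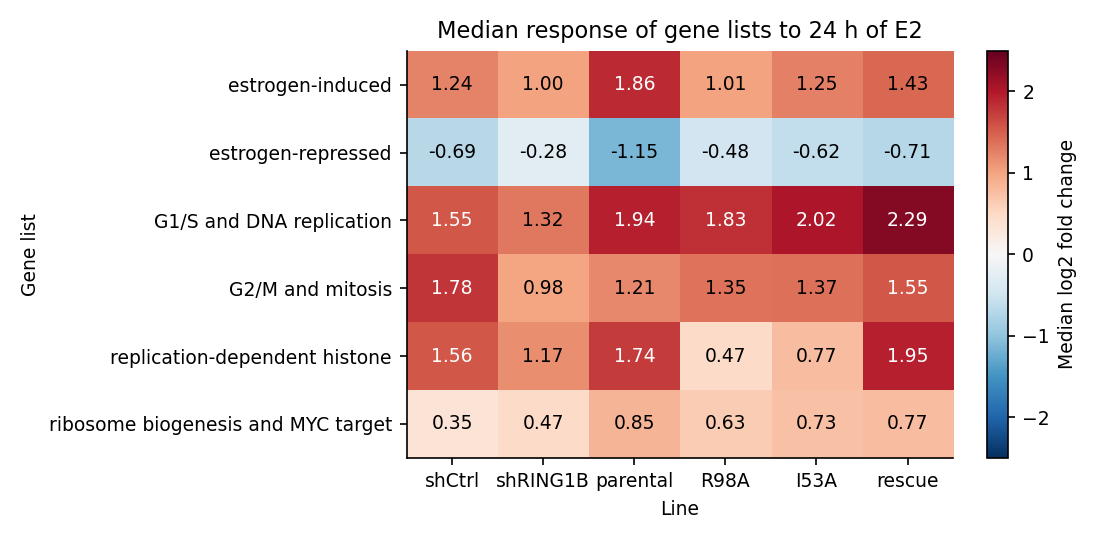
Median log2 fold change after 24 h of E2 of the members of 6 gene lists (vertical) in 6 lines (horizontal), printed in each cell of a heat map. Estrogen-induced genes have medians from 1.00 to 1.86 and estrogen-repressed genes from -1.15 to -0.28.

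Both mutant lines differed from parental cells at 0 h, largely in shared genes. PEG10 was higher by 3.92 ± 0.16 in R98A (adjusted p = 1.5e-09) and by 3.76 ± 0.16 in I53A (adjusted p = 2.5e-09), and SLITRK6 by 3.94 ± 0.39 and 4.23 ± 0.39 (adjusted p = 0.00027 and 0.00025). GLDC, a glycine cleavage gene, was lower by -3.02 ± 0.19 and -3.03 ± 0.20 (adjusted p = 5.3e-08 and 1e-07). LMO3, ANK2, LRP1B and COLCA1 were higher in both (3.40 to 4.57), and SLC7A5, JPH2, ABCA13 and KRT4 lower in both (-4.18 to -3.02). G2/M and mitosis genes were lower in 30 of 30 in each, with medians of -2.26 and -2.03 (30 adjusted over the list alone; adjusted p = 0.36 and adjusted p = 0.34 with an estimated correlation). UBE2C, which drives mitotic exit, was at -2.51 ± 0.17 in both lines. G1/S and DNA replication genes were lower in 29 of 30 in each (29 adjusted over the list alone; adjusted p = 0.36 and adjusted p = 0.34 with an estimated correlation). ESR1 was lower by -0.57 ± 0.11 in R98A (adjusted p = 0.0013) and -0.51 ± 0.11 in I53A (adjusted p = 0.0037). Of 19655 tested genes, 6310 were called for R98A (2988 higher) and 5158 for I53A (2197 higher) at 0 h, and 6150 (2651 higher) and 5695 (2418 higher) at 24 h.

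Genes called in both mutant lines against parental numbered 1914 higher and 2630 lower at 0 h, where independent calls would share 334 and 500.5. At 24 h they numbered 2070 and 2911, where independent calls would share 326.1 and 583.4. At most 1 gene was called in opposite directions. At an unadjusted p under 0.05, simulated counts with no change shared on average 75.6 to 114 genes by way of the common controls, where independent calls would share 11.8, and the observed numbers were 2835 to 3741. Both comparisons use the parental libraries, which could not be divided, and both lines differ from parental also in the hairpin, vector, selection and sorting. The counts moved to 4119 and 4079 for R98A at 0 h (without parental replicate 1 or R98A replicate 2), and to 3297 and 3262 for I53A (without parental replicate 1 or I53A replicate 2). At 24 h they moved to 3739, 3325 and 3791 for I53A at 24 h (without parental replicate 1, I53A replicate 1 or I53A replicate 2).

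Set against each other, R98A and I53A differed in fewer genes than either did from parental. RNF2 was lower in R98A than in I53A at 0 h (-1.82 ± 0.17, adjusted p = 0.0042) and 24 h (-1.53 ± 0.17, adjusted p = 0.026). SCN1A, a neuronal sodium channel gene, was lower at both times (-2.66 ± 0.35, adjusted p = 0.0071, and -2.46 ± 0.36, adjusted p = 0.026). So were RBMS3, an RNA-binding protein gene (-3.86 ± 0.47, adjusted p = 0.0047, at 0 h), FSTL5 and LPHN3. These 4 genes, all with few counts, were chosen after their values were seen. CLSTN2, a calsyntenin gene, was higher in R98A at 0 h (0.90 ± 0.13, adjusted p = 0.015). The counts were 11 genes at 0 h (4 higher, 7 lower) and 6 at 24 h (1 higher, 5 lower), or 7 at 24 h (2 higher, 5 lower) with DESeq2 size factors. With no filter they were 109 and 47, and with the axis 75 and 11. Without R98A replicate 1 or R98A replicate 2 the count was 0 at both times, and without I53A replicate 2 it was 6 at 0 h and 0 at 24 h. The call of RNF2 was lost at 0 h without R98A replicate 1 (-1.70, adjusted p = 0.067) or replicate 2 (-1.95, adjusted p = 0.068), and at 24 h without R98A replicate 1 (adjusted p = 0.51), R98A replicate 2 (0.1) or I53A replicate 2 (0.23). CLSTN2 was lost without R98A replicate 1 (adjusted p = 0.29), R98A replicate 2 (0.13) or I53A replicate 1 (0.15). G2/M and mitosis genes had a median of -0.24 at 0 h (camera adjusted p = 0.00022, but adjusted p = 0.85 with an estimated correlation). True 2-fold changes were recovered in 64.2% of simulated cases at 24 h.

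The classical targets rose after E2 in both mutant lines. PGR rose by 2.08 ± 0.14 in R98A and 1.98 ± 0.14 in I53A (adjusted p = 1.9e-07 and 2.4e-07). GREB1 rose by 1.66 ± 0.17 and 2.13 ± 0.17 (adjusted p = 5.4e-05 and 7.1e-06), and ESR1 by 0.81 ± 0.11 and 0.75 ± 0.11 (adjusted p = 0.00023 and 0.00041). TFF1 rose by 4.68 ± 0.73 and 4.62 ± 0.78 (adjusted p = 0.0077 and 0.0094), calls that were lost without 0 h replicate 1 of the line (4.05, adjusted p = 0.051, and 4.04, adjusted p = 0.06). Estrogen-induced genes rose in 25 of 34 in R98A and 27 in I53A (26 and 29 adjusted over the list alone; adjusted p = 0.0044 and adjusted p = 0.0052 with an estimated correlation). All 30 G1/S and DNA replication genes rose in each (30 adjusted over the list alone; adjusted p = 0.031 and adjusted p = 0.023 with an estimated correlation). More genes were called with the axis of replicate differences in both lines, and with the replicate block in R98A, as listed in the section on processing. As reported, calls numbered 2202 in R98A (1655 higher, 547 lower) and 2431 in I53A (1811 higher, 620 lower). They were 941, 1035 and 1009 in R98A without 0 h replicate 1, 0 h replicate 2 or 24 h replicate 1. They were 1616, 1485 and 1129 in I53A without 0 h replicate 2, 24 h replicate 1 or 24 h replicate 2.

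The E2 response of each mutant line differed from that of parental cells. MYB, at 3.016 CPM in parental and 14.78 and 15.91 in R98A and I53A at 0 h, reached 27.64, 26.26 and 24.33 CPM at 24 h. The difference was -2.35 ± 0.23 for R98A (adjusted p = 0.00024) and -2.56 ± 0.23 for I53A (adjusted p = 0.00016). HSPB8, a small heat shock protein gene, differed by -1.85 ± 0.23 and -1.96 ± 0.23 (adjusted p = 0.0011 and 0.0014), and ASNS, the asparagine synthetase gene, by -1.48 ± 0.17 and -1.23 ± 0.17 (adjusted p = 0.00052 and 0.0033). CDH10, a cadherin gene, differed by 1.84 ± 0.18 in R98A (adjusted p = 0.00024) and FBXO32 by 1.59 ± 0.21 (adjusted p = 0.003), where the responses of parental cells were -1.93 and -2.29. Estrogen-induced genes rose less in 9 of 34 in R98A (15 adjusted over the list alone, with 2 that rose more; camera adjusted p = 1.8e-07, but adjusted p = 0.084 with an estimated correlation). They did so in 3 in I53A (10 adjusted over the list alone, with 2 that rose more; adjusted p = 0.15 with an estimated correlation). As sets chosen in shCtrl, 738 repressed genes fell less in R98A (median difference 0.38, 87.9% above 0, fry adjusted p = 4.3e-05) and in I53A (0.34, 87%, fry adjusted p = 4.3e-05). The 1309 induced genes had median differences of -0.18 and -0.15 (fry adjusted p = 0.22 and 0.25). They passed with the axis of replicate differences as a covariate, a setting added after seeing the data (-0.24 and -0.17, fry adjusted p = 0.014 and 0.046), and in R98A with the 100 genes of largest change (-0.6, fry adjusted p = 0.042). The axis was taken from the spread of these same libraries, so a smaller spread is built into that setting.

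Differences from parental were called for 724 genes in R98A (287 higher, 437 lower) and 154 in I53A (78 higher, 76 lower). With no filter the counts were 1462 and 556, and with the axis 2316 and 1024. The replicate number as a block also gave more calls in both lines, as listed in the section on processing. The count for R98A was 248, 340 and 427 without parental 0 h replicate 1, 0 h replicate 2 or 24 h replicate 2. It was 178, 140 and 166 without R98A 0 h replicate 1, 0 h replicate 2 or 24 h replicate 1. For I53A it was 97, 64 and 53 without parental 0 h replicate 1, 0 h replicate 2 or 24 h replicate 1, and it was 68, 46 and 29 without I53A 0 h replicate 2, 24 h replicate 1 or 24 h replicate 2. Between R98A and I53A edgeR called 0 differences of response (545 genes at an unadjusted p under 0.05; 0 by DESeq2's Wald test). The count was 34 with no filter, 4 with only the compared groups and 1 with the axis. Their repressed and induced sets had median differences of 0.05 and -0.03 (fry adjusted p = 0.24 and 0.8).

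Genes also changed after E2 in cells that carried the hairpin and wild-type RING1B. CXCL12 rose by 5.98 ± 0.20 in rescue (adjusted p = 2e-08), OLFM1 by 5.02 ± 0.23 (adjusted p = 5.2e-07), and SERPINA6 by 4.08 ± 0.25 (adjusted p = 1.4e-05). PGR rose by 1.94 ± 0.12 (adjusted p = 4.9e-06), GREB1 by 2.60 ± 0.16 (adjusted p = 7.6e-06) and ESR1 by 0.85 ± 0.12 (adjusted p = 0.00067). ITGB8, an integrin gene, fell to -1.91 ± 0.21 (adjusted p = 0.00016), and ABCA1 to -1.81 ± 0.26 (adjusted p = 0.0012). Estrogen-induced genes rose in 29 of 35 (34 adjusted over the list alone; adjusted p = 0.012 with an estimated correlation). Ribosome biogenesis and MYC target genes rose in 26 of 30 (29 adjusted over the list alone; adjusted p = 0.012 with an estimated correlation), with MYC at 3.05 ± 0.30. All 30 G1/S and DNA replication genes rose (30 adjusted over the list alone, adjusted p = 0.16 with an estimated correlation). With only the compared groups in the fit, or with the axis of replicate differences, more genes were called, as listed in the section on processing. Calls numbered 2431 (1778 higher, 653 lower), and 749, 1132 and 828 without 0 h replicate 1, 0 h replicate 2 or 24 h replicate 2. The rise of TFF1 (3.50 ± 0.78, adjusted p = 0.027) was lost without 24 h replicate 1 (3.77, adjusted p = 0.072) or 24 h replicate 2 (3.18, adjusted p = 0.17).

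Gene by gene, the response of rescue was compared with those of shRING1B and shCtrl. Against shRING1B the test called 0 differences with edgeR (1555 genes at an unadjusted p under 0.05; 38 by DESeq2's Wald test), 15 with no filter, 2 with the axis and 1 with only the compared groups. The count was 7 without shRING1B 0 h replicate 2, 5 without rescue 24 h replicate 1, and 1 without shRING1B 24 h replicate 1, rescue 0 h replicate 2 or rescue 24 h replicate 2. The median difference was 0.28 for induced and -0.17 for repressed genes (fry adjusted p = 0.14 and 0.21). Against shCtrl 5 genes were called, of which GRPR, TRIM59 and DNAJC25-GNG10 were chosen after their values were seen. Higher were CXCL12 (2.02 ± 0.25, adjusted p = 0.029), and the bombesin receptor gene GRPR (1.99 ± 0.26, adjusted p = 0.029). Lower were TRIM59 (-1.32 ± 0.17, adjusted p = 0.029), AREG (-4.61 ± 0.47, adjusted p = 0.0093) and the readthrough gene DNAJC25-GNG10 (-6.68 ± 0.89, adjusted p = 0.029). DESeq2's Wald test called 185, and edgeR 123 with no filter, 138 with the axis and 2 with only the compared groups. That count of 5 was 1 without either shCtrl 0 h library, 14 and 18 without shCtrl 24 h replicate 1 or 2. It was 2 and 3 without rescue 0 h replicate 1 or 2, and 25 and 0 without rescue 24 h replicate 1 or 2. In that comparison ESR1 was at 0.98 ± 0.16 (adjusted p = 0.056).

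The levels in rescue were compared with shRING1B to see which knockdown changes were undone. BCHE was lower by -4.45 ± 0.18 (adjusted p = 5e-08) and PPP1R3C, a glycogen-targeting gene, by -4.84 ± 0.24 (adjusted p = 1.8e-07), so that BCHE stood at 4.66 CPM in rescue and 4.09 in shCtrl at 0 h. Other genes stayed near their level in shRING1B: BCL2 stood at 0.56 CPM in rescue, 0.38 in shRING1B and 17.6 in shCtrl, and SERPINA6 at 4.35, 4.65 and 131 CPM. Parental cells, which carry no hairpin, were also lower than shCtrl at 0 h, by -1.58 ± 0.22 for BCL2 and -2.85 ± 0.17 for SERPINA6. Against parental, rescue was at -3.28 ± 0.27 and -1.97 ± 0.19, so the size of the gap depended on the reference. STC1 and CLSTN2 were lower (-5.03 ± 0.26 and -3.82 ± 0.34), and KRT4, a keratin gene, was higher by 5.40 ± 0.81 (adjusted p = 9e-04). Developmental Polycomb target genes were higher in 19 of 33 and lower in 1 (19 and 1 adjusted over the list alone; camera adjusted p = 1e-05, but adjusted p = 0.24 with an estimated correlation), with HOXC8 at 1.73 ± 0.19. PRC1 subunit genes were higher in 10 and lower in 3 (10 and 3 adjusted over the list alone, camera adjusted p = 0.018, but adjusted p = 0.24 with an estimated correlation), with AUTS2 at 2.15 ± 0.15. RNF2, the gene of the PRC1 subunit that the construct supplies, was itself at 5.50 ± 0.18 in this comparison. G2/M and mitosis genes were lower in 29 of 30 (29 adjusted over the list alone; adjusted p = 0.57 with an estimated correlation), with TOP2A at -1.86 ± 0.23. Mitochondrially encoded genes were higher in 12 of 13 (12 adjusted over the list alone, camera adjusted p = 1.7e-12, but adjusted p = 0.32 with an estimated correlation), with MT-ND6 at 3.81 ± 0.16. The share of all counts in mitochondrial genes differed less at 0 h. It was 6.651% and 7.472% in the rescue libraries, and 5.78% and 6.571% in those of shRING1B.

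In all, 7754 genes differed from shRING1B at 0 h (3601 higher) and 5688 at 24 h (2871 higher), and 9456 (4447 higher) and 9253 (4632 higher) from shCtrl. The counts against shRING1B were 4740, 4644 and 4947 at 0 h without shRING1B replicate 1, rescue replicate 1 or rescue replicate 2, and 2468, 3596 and 2770 at 24 h without shRING1B replicate 1, rescue replicate 1 or rescue replicate 2. Among called genes that differed at least 2-fold, more were higher than lower in rescue. Against shRING1B 2311 were higher and 1151 lower at 0 h, and 1717 and 813 at 24 h. Against shCtrl 2828 were higher and 2022 lower at 0 h, and 2843 and 1818 at 24 h. The rescue libraries came from 250 ng of RNA and the others from 500 ng, so that line and library batch cannot be told apart in these levels. CEBPA, a differentiation factor gene, was at 19.29 ± 0.341 CPM in rescue and at 0 in shRING1B and shCtrl at 0 h (SD, n = 2). JUND, an AP-1 factor gene, was at 142.2 ± 10 CPM against 13.37 ± 1.62 in shRING1B.

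**Figure D4:**
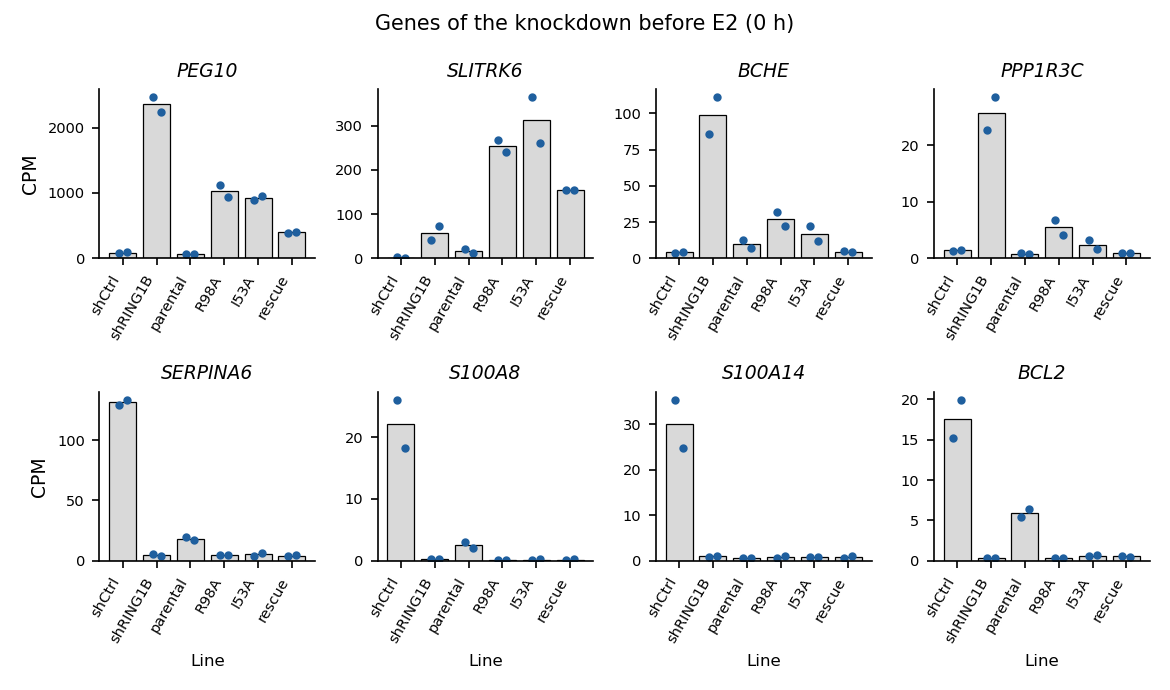
CPM at 0 h in the 6 lines for 8 of the genes named for the knockdown, which are not the 8 of largest change. Bars are means and points the 2 libraries. PEG10 stands at 2354 in shRING1B, 398 in rescue and 82.2 in shCtrl, and BCL2 at 0.38, 0.56 and 17.6.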

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

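The differences between E2 responses were planned, except that of rescue against parental, and so were the tests of the starting levels; the test with the axis of replicate differences as a covariate was added after seeing the data.

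Results below stood out because the E2 responses of 2 lines differed by a test of the difference itself. Between shRING1B and shCtrl edgeR called 1 gene at 4 h, 2 at 8 h, 3 at 12 h and 3 at 24 h. At 24 h PPM1K rose more in shRING1B (1.26) and THBS1 differed by -1.67. THBS1 stood at 193.9 CPM in shCtrl and 675.4 in shRING1B at 0 h, and its calls at every time rest on those same 0 h libraries. PPM1K reached 129.6 CPM in shRING1B, 253.8 in R98A, 250.8 in I53A and 151.8 in rescue at 24 h, against 63.99 in shCtrl and 97.14 in parental, which was noticed after the values were seen.

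Between R98A and parental 724 genes were called. The genes of largest positive difference were RANBP3L at 1.87, CDH10 at 1.84, CLDN8 at 1.78, KCNH7 at 1.66, DACH1 at 1.65, NEK10 at 1.64, FBXO32 at 1.59 and PAQR5 at 1.58. Those of largest negative difference were HIST1H4J at -2.98, CBS at -2.46, MYB at -2.35, SLC16A3 at -2.22, HIST2H2AA4 at -2.21, CT62 at -2.14, MCAM at -2.04 and ITPK1 at -2.03. MYB, CBS, which makes cystathionine, and ITPK1, an inositol kinase gene, kept their calls without any 1 library, while those of PAQR5, NEK10 and HIST1H4J were lost in at least 5 such cases. Between I53A and parental 154 genes were called, and between rescue and shCtrl 5.

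Genes repressed after E2 fell less in several lines that carry the RNF2 hairpin. In shRING1B against shCtrl the median difference was 0.20, 0.11, 0.29 and 0.16 at 4, 8, 12 and 24 h, and of these the 12 h value passed (fry adjusted p = 0.14, 0.24, 0.026 and 0.14). Against parental it was 0.38 in R98A and 0.34 in I53A (fry adjusted p = 4.3e-05 for each). Rescue stood at -0.01 against shCtrl (fry adjusted p = 1) for 2396 genes chosen in parental, as for shRING1B. For 740 genes chosen in shCtrl, as for the mutants, it stood at 0.19 against parental (fry adjusted p = 4e-04) in a fit of the parental, mutant and rescue libraries. The main axis of replicate differences held 20.5% of the variance within groups. With that axis as a covariate the 12 h value was 0.23 (fry adjusted p = 0.011). Its median thus did not rest on that axis alone. The axis was taken from the spread of these same libraries, so a smaller spread is built in and the p-value is no separate support. The rest of the spread between replicates was not tested as a covariate. As sets, the repressed genes had medians near 0 at 0 h. Their median log2 fold change was 0 (quartiles -0.40 and 0.35) in shRING1B against shCtrl. It was 0.02 (-0.46 and 0.39) in R98A and -0.01 (-0.43 and 0.35) in I53A against parental. These medians lay above the planned bounds, which asked for a median below 0, but the lower quartiles lay under those bounds. By their medians the sets did not start lower. Single genes went both ways, so the test cannot exclude a lower start of some of them. In R98A and I53A the vector, the sorting and the hairpin differ from parental together and cannot be told apart. Whether RING1B accounts for the weaker fall stays open, and the 12 h call was lost without any 1 of 5 libraries (fry adjusted p of 0.064 to 0.093). Which time passed also depended on the setting: with the 100 genes of largest change 12 h missed the threshold (0.52, fry adjusted p = 0.082) and 24 h passed (0.67, 0.037). The 24 h value also passed with the axis (0.18, 0.025) and without both far shCtrl libraries (0.24, 0.048).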

How the results depend on the processing

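The setting with the main axis of replicate differences as a covariate, and the E2 strength without both shCtrl 8 h replicate 1 and shCtrl 24 h replicate 1, were chosen after seeing the data, and the other tests were planned. Scaling by spike-ins was not run, since the files hold none. With the size factors of DESeq2 all 37 counts stayed within 1.5 times their value. Counts moved beyond that in 14 of 37 comparisons with the Wald test, 18 with no filter, 14 with the replicate block, 25 with the axis and 19 of 36 with only the compared groups in the fit. They also moved in 118 of 200 cases of leaving out 1 library, where fewer samples leave less power and the lone sample is assumed to vary like the other groups. The axis was taken from the spread within groups of the same libraries, so a smaller spread is built into that setting. For the other settings the cause was not tested. The libraries were not taken as paired by replicate number, since not every correlation between groups was above 0.1: 6 of 45 were in the shCtrl and shRING1B fit, 7 of 15 in the mutant fit and 3 of 15 in the rescue fit. Under -0.1 lay 0, 0 and 1 in the same order. The correlations thus leaned to the positive side, so this rule does not exclude a difference shared by replicate number, which the reported counts leave out. In the mutant fit replicate 2 lay above replicate 1 along the main axis in all 6 groups, a hint from the data of a shared difference. Of 979 named results that passed, 11688 values under alternatives gave 10862 with the call kept, 826 with it lost and 0 reversed. At this depth and with 2 libraries per group, neither of which was varied, true 2-fold differences between the E2 responses of shRING1B and shCtrl at 24 h were recovered in 14.9% of simulated cases and 4-fold ones in 66.7%.

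With DESeq2's Wald test E2 gave 236, 654 and 1353 genes in shCtrl at 4, 8 and 12 h and 275, 134, 313 and 951 in shRING1B at 4, 8, 12 and 24 h. The differences gave 9, 14, 25 and 56 between shRING1B and shCtrl, 297 for I53A, 38 for rescue minus shRING1B and 185 for rescue minus shCtrl. With no filter, in the same order, E2 gave 340, 674 and 1751, then 540, 364, 546 and 1096, and the differences 231, 107, 270 and 158. R98A against I53A gave 109 and 47, and the differences were 1462 for R98A, 556 for I53A, 34 for R98A minus I53A, 15 for rescue minus shRING1B and 123 for rescue minus shCtrl.

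With the axis as a covariate E2 gave 339, 1375, 1743 and 4160 genes in shCtrl at 4, 8, 12 and 24 h, 318, 225, 704 and 1400 in shRING1B, 3856 in R98A, 4234 in I53A and 3943 in rescue. The knockdown gave 4898, 5473 and 5580 at 0, 8 and 24 h, R98A against I53A 75 and 11, and the differences 5, 11, 13 and 61 for shRING1B, 2316 for R98A, 1024 for I53A, 1 for R98A minus I53A, 2 for rescue minus shRING1B and 138 for rescue minus shCtrl. The median differences that passed with it and not as reported were 0.18 for repressed genes in shRING1B at 24 h (fry adjusted p = 0.025), and -0.24 and -0.17 for induced genes in R98A and I53A (fry adjusted p = 0.014 and 0.046). That of repressed genes in rescue minus shCtrl turned to 0.02.

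With only the compared groups in the fit E2 gave 301, 36, 4017 and 1312 genes in shCtrl at the 4 times, 40 and 479 in shRING1B at 4 and 12 h and 4249 in rescue. The knockdown gave 4448, 548, 6941 and 1955 at 0, 8, 12 and 24 h, and R98A against I53A 21 at 24 h. The differences gave 4, 1 and 411 for shRING1B at 4, 8 and 12 h, 91 for I53A, 4 for R98A minus I53A, 1 for rescue minus shRING1B and 2 for rescue minus shCtrl. With the replicate block E2 gave 472 and 1143 in shCtrl at 8 and 12 h, 128, 98 and 208 in shRING1B at 4, 8 and 12 h and 3421 in R98A. R98A against I53A gave 28 and 10, and the differences 4, 12 and 13 for shRING1B at 8, 12 and 24 h, 1838 for R98A, 561 for I53A and 14 for rescue minus shCtrl.

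With the 100 genes of largest change per set the repressed genes of shRING1B had a median difference of 0.52 at 12 h (fry adjusted p = 0.082) and 0.67 at 24 h (0.037), the induced genes of R98A -0.6 (0.042), and the repressed genes of rescue -0.38 against shRING1B (0.025) and 0.01 against shCtrl (0.95). Without both far shCtrl libraries the repressed genes of shRING1B differed by 0.24 at 24 h (fry adjusted p = 0.048). With DESeq2's size factors the repressed genes of rescue minus shCtrl stood at 0. Of 814 list tests 277 passed camera, 40 passed with an estimated correlation and 252 passed fry. Both camera and fry passed in the same direction in 177 tests, and in opposite directions in 0. Among genes changed at least 1.5-fold, R98A and I53A shared 1644 lower genes at 0 h, and 1304 higher and 1827 lower ones at 24 h.

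Leaving out 1 library gave these lowest and highest counts. E2 in shCtrl ranged from 40 to 57, 88 to 369, 113 to 251 and 875 to 1564 at the 4 times, and E2 in shRING1B from 26 to 45, 29 to 50, 49 to 100 and 117 to 413. The knockdown ranged from 1330 to 1830, 2089 to 3189, 2038 to 3901, 2003 to 2372 and 1822 to 3183 at the 5 times and from 8916 to 9922 on average. E2 in parental ranged from 4103 to 4839, in R98A from 941 to 1638, in I53A from 1129 to 1717 and in rescue from 749 to 1720. Against parental R98A ranged from 4079 to 5481 and 4368 to 4807 at 0 and 24 h, I53A from 3262 to 4703 and 3325 to 4485, and R98A against I53A from 0 to 8 and 0 to 4. Rescue ranged from 4644 to 5992 and 2468 to 3932 against shRING1B and from 6411 to 7305 and 6377 to 9676 against shCtrl. Differences ranged from 0 to 3, 1 to 3, 0 to 3 and 0 to 5 for shRING1B, 140 to 711 for R98A, 29 to 197 for I53A, 0 to 1 for R98A minus I53A, 0 to 7 for rescue minus shRING1B and 0 to 25 for rescue minus shCtrl.

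Median differences of induced genes without 1 library ranged from -0.21 to -0.01, -0.12 to 0.02, -0.3 to -0.13 and -0.2 to -0.05 for shRING1B at the 4 times, -0.28 to -0.07 for R98A, -0.25 to -0.06 for I53A, -0.09 to 0.04 for R98A minus I53A, 0.21 to 0.37 for rescue minus shRING1B and 0.11 to 0.28 for rescue minus shCtrl. Those of repressed genes ranged from 0.14 to 0.23, 0.02 to 0.21, 0.21 to 0.34 and 0.08 to 0.24 for shRING1B, 0.36 to 0.4 for R98A, 0.31 to 0.37 for I53A, 0.02 to 0.05 for R98A minus I53A, -0.22 to -0.1 for rescue minus shRING1B and -0.08 to 0.07 for rescue minus shCtrl. Signs turned for induced genes of shRING1B at 8 h without shCtrl 0 h replicate 2 (0.01) or shRING1B 0 h replicate 1 (0.02), of R98A minus I53A without R98A 24 h replicate 2 (0) or I53A 0 h replicate 2 (0.04), and for repressed genes of rescue minus shCtrl without shCtrl 24 h replicate 1 (0.07), rescue 0 h replicate 1 (0), rescue 0 h replicate 2 (0.01) or rescue 24 h replicate 2 (0.03).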

Other observations

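The tests of whether RNF2 was restored, of the experiments for the mutant lines, of a lasting hairpin effect, of a return to an earlier level and of a library difference in rescue were chosen only after the result was seen; the tests of other splits of the libraries and of rescue against the mutants were planned.

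Beyond estrogen targets, single genes of other kinds differed with the knockdown over the 5 times. No list of the 22 held its call with an estimated correlation, while 17 passed fry. KRT8 and KRT18, the paired keratins of luminal cells, were lower in shRING1B by -2.08 ± 0.10 and -1.91 ± 0.07 (adjusted p = 4e-11 and 4.3e-13). These SE rest on 2 libraries per line at each of the 5 times and do not measure variation between lines. Luminal epithelial markers, though, split into 7 higher and 8 lower of 22 (7 and 8 adjusted over the list alone, camera adjusted p = 0.88). Basal epithelial markers were lower in 7 of 14 and higher in 2 (7 and 3 adjusted over the list alone; camera adjusted p = 0.049, but adjusted p = 0.34 with an estimated correlation), with KRT15 at -2.24 ± 0.09. Interferon response genes were higher in 21 of 35 and lower in 4 (21 and 4 adjusted over the list alone; camera adjusted p = 0.00014, but adjusted p = 0.31 with an estimated correlation), with HERC6 at 1.42 ± 0.12 (adjusted p = 2.2e-08) and PARP9 at 0.88 ± 0.06 (adjusted p = 4.9e-09). NF-kB and inflammatory genes were lower in 8 of 14 and higher in 2 (9 and 2 adjusted over the list alone; camera adjusted p = 0.0088, but adjusted p = 0.31 with an estimated correlation), with LCN2, an iron-binding lipocalin gene, at -2.58 ± 0.28. Immediate early genes were lower in 14 of 21 and higher in 4 (14 and 4 adjusted over the list alone; camera adjusted p = 0.0017, but adjusted p = 0.33 with an estimated correlation), with IER3 at -2.42 ± 0.11, and p53 target and apoptosis genes split into 7 and 7 (7 and 8 adjusted over the list alone; camera adjusted p = 0.88).

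Members of metabolic lists also differed with the knockdown. Hypoxia and glycolysis genes were lower in 13 of 20 and higher in 4 (13 and 4 adjusted over the list alone; camera adjusted p = 0.0018, but adjusted p = 0.33 with an estimated correlation), with the enolase gene ENO1 at -1.40 ± 0.06 (adjusted p = 3.5e-12). Cholesterol and lipid synthesis genes were higher in 15 of 26 and lower in 1 (16 and 3 adjusted over the list alone; camera adjusted p = 0.0012, but adjusted p = 0.25 with an estimated correlation), with DHCR7, the last enzyme of cholesterol synthesis, at 0.81 ± 0.08. Unfolded protein response and ATF4 target genes were higher in 13 of 23 and lower in 4 (14 and 4 adjusted over the list alone; camera adjusted p = 0.0076, but adjusted p = 0.31 with an estimated correlation), with ASNS at 1.03 ± 0.09, and mitochondrially encoded genes were higher in 4 of 13 (4 adjusted over the list alone; camera adjusted p = 0.024, but adjusted p = 0.51 with an estimated correlation). Estrogen receptor cofactor and luminal transcription factor genes split into 10 higher and 6 lower (10 and 7 adjusted over the list alone; camera adjusted p = 0.78), and mesenchymal and fibroblast markers into 6 and 8 (7 and 8 adjusted over the list alone; camera adjusted p = 0.88). Of 16 leukocyte markers 4 could be tested, and 2 were lower (2 adjusted over the list alone; camera adjusted p = 0.48).

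In 100 splits of the 20 shCtrl and shRING1B libraries, only the real split gave as many called genes (1 of 100). It gave 9557, against 4189 in the highest other split. Every other split mixed the lines, which moves the difference between them into the spread within groups, so lower counts were built in. The splits therefore cannot decide whether chance accounts for the count. All libraries of a line are repeats of that line, so a chance difference between the lines was not tested. The highest other split had 16 of the 20 libraries in their real place.

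Genes that differed between shRING1B and shCtrl were in part shifted as well in lines that carry the hairpin and express RING1B again. The amount depended on the reference. The 680 genes lower in shRING1B, chosen at 4, 8 and 12 h, had a median at 0 h of -1.05 in rescue against shCtrl and of 0.39 in rescue against shRING1B. Against parental it was -0.31 in rescue, with 200 of them called higher and 294 lower. The 484 higher genes had medians of 1.02, -0.25 and 0.41 in the same order. RNF2 was not missing, since its lowest log2 fold change in these lines was 2.37. Parental against shCtrl gave medians of -0.85 and 0.54 for the 2 sets, which could account for part of the rescue result. These 2 lines differ in experiment, RNA input and the control hairpin together, and the genes were chosen against shCtrl, so what shifted them was not separated. A difference between experiments does not account for R98A, which stood at -0.73 against parental within its own experiment. A lasting effect of the hairpin or of line selection, and RING1B that is expressed but does not act, cannot be told apart here, since no line had the hairpin removed and no protein was measured.

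A set of 9 genes stood near 0 in every other line and was abundant in rescue, all chosen after their values were seen. The most abundant was MIR3648, a small RNA gene, at 248.13 CPM (mean over 0 and 24 h, scaled by the library totals). Among the others were CEBPA at 20.16 CPM, LRRC26 at 10.77 and PRR7 at 6. They did not return to the level of cells with their own RING1B, which was at most 0.34 CPM on average in shCtrl or parental. The number of such genes, 9, could also come from a difference in the libraries or counting of rescue, which cannot be told apart from the line, and GC content was not tested for want of a genome sequence.

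It was also asked whether wild-type RING1B gave a larger E2 response than the mutants, with sets chosen in shCtrl. The prediction held in 2 of 4 tests: repressed genes fell more in rescue than in R98A (median difference -0.19, fry adjusted p = 4e-04) and than in I53A (-0.15, fry adjusted p = 0.001), while induced genes had median differences of 0.13 and 0.08 (fry adjusted p = 0.44 and 0.5). The same genes fell less in rescue than in parental (0.19, fry adjusted p = 4e-04). Rescue and the mutants may differ by their libraries as well as by RING1B, which 2 of 4 tests do not settle.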
